A study of Homo sapiens with 32 samples.

How the data were processed

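Total RNA of the human liver tumour lines Huh7 and HepG2 was labelled with biotin and read on 32 Illumina expression bead arrays, 4 in each of 8 groups. The groups were Huh7 and HepG2 with DMSO or SAHA, and Huh7 and HepG2 with scrambled siRNA or HDAC2 siRNA, as the sample titles and characteristics give them. The dose, the time of treatment and the siRNA sequence are not given in the sources used here. GenomeStudio 2011.1 is named per the submitters' processing notes; which of its steps were used for which table is not given in the sources used here.

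The authors deposited a table of probe intensities on a linear scale, without background subtraction and with a different distribution on each array. Per the file headers, the same table holds a detection p-value for each probe on each array, a measure of its signal against negative control beads, here in 664 distinct steps. The authors also deposited a table of intensities that all share one distribution over the 32 arrays and go down to -32.7, with 23.0% of values at or below 0, so its values had been background-subtracted and quantile-normalized on a linear scale. Within an array both tables ordered the probes alike (rank correlation 1). The table without normalization was used, and the normalized table served as an alternative.

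Each of 24526 probes carried a gene symbol of 18402 in all. Of the probes, 20406 bore a current symbol of the reference gene list, 3265 an older symbol of 1 gene, which was brought up to date, and 855 a symbol that was not matched and was kept as it stood. The reference list was used for symbols only, and no positions were used. Intensities were processed in R 4.3.3 with limma 3.58.1. The background of each array was estimated from the detection p-values and removed by the normexp method, an offset of 16 was added, and the 32 arrays were quantile-normalized together and put on the log2 scale. A probe entered when its detection p was under 0.05 on at least 4 arrays (16121 probes). A gene was tested by its probe with the highest mean over all arrays, which gave 12973 genes, 2384 of them with more than 1 detected probe. The median signal of an array before normalization ran from 118.2 to 195.5, and arrays of one group correlated at 0.979 to 0.996.

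One limma model with the 8 group means was fitted to all 32 arrays (24 residual degrees of freedom and 5.66 from the prior), since 4 arrays give few on their own. It gave the 4 treatment comparisons, the interaction contrasts between lines (HepG2 effect minus Huh7 effect) and between treatments (SAHA effect minus siRNA effect), each with two-sided moderated tests and Benjamini-Hochberg adjustment over the genes tested; a gene was called at an adjusted p under 0.05. Where no array of one group had a detection p under 0.05 for a probe, a bound on the fold was computed with the signals of that group raised to at least the lowest detected signal of their array, which was 5.22 to 5.55 on the log2 scale, and the text gives it as "at least". The labels name no batch, and nothing in them pairs the arrays of one group with those of another.

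Gene lists were tested with limma camera at a preset correlation of 0.01, adjusted over the 31 lists of a comparison, with an estimated correlation beside it, and with limma fry as an alternative. The lists were the HDAC family, corepressor complexes, cell cycle inhibitors, DNA replication, mitosis, p53 targets, pro-apoptotic genes, anti-apoptotic genes, hepatocyte genes, hepatocyte transcription factors, oncofetal liver genes, PPAR and fatty acid oxidation, fatty acid synthesis, cholesterol synthesis, glycolysis and glucose transport, gluconeogenesis, insulin and mTOR signalling, interferon response, integrated stress and unfolded protein response, heat shock, NRF2 targets, metallothioneins, histone genes, WNT targets, MYC and ribosome biogenesis, epithelial and mesenchymal genes, neuronal genes, cancer testis genes, leukocyte markers, fibroblast and endothelial markers, and reference genes. They held 664 genes, 650 of them among the probes' symbols and 581 tested. The text names HDAC2 and its family; the 12 genes with the largest rise and the 12 with the largest fall of each treatment comparison, leaving out symbols that are only clone or locus identifiers; the 8 largest differences in each direction of each line contrast; the first 10 genes per direction called alike in all 4 comparisons, ranked by their smallest change; and up to 4 members of each list with the smallest adjusted p. Of these, fewer are printed, in rank order, and some are not reported here. Lists, tests, thresholds, naming rule and alternatives were fixed before the data were examined, except where the text says otherwise.

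Alternatives left out background correction, scaled each array to one median in place of quantile normalization, normalized within one line, used the authors' normalized values, tested all genes without a detection filter or only those detected on all 32 arrays, took the mean of a gene's probes or all probes singly, and asked for an adjusted p under 0.01 or a change of at least 2-fold. Others blocked the arrays by replicate number, weighted arrays by quality, used an intensity trend with a robust prior, fitted only the arrays of a comparison, or left out each array in turn. Under the other normalizations each gene kept the probe of the main settings; this was set after a choice of probe under each setting had been seen to swap the probe of CALB2 and of CD3D. The same tests on other splits of the arrays gave counts to set beside those of the real groups.

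The procedure was tested on simulated data with the same group sizes. Each gene had 1 spread, pooled over the groups of these arrays, although the groups differed in spread. Genes were drawn without correlation, and far fewer were changed than were called in the real comparisons. Among genes given a change of 0.5 on the log2 scale, 38.2% to 47.8% were called across the 4 comparisons, among those given 1 it was 92.6% to 94.9%, and at 2 it was 100%. Of 12973 genes per simulated comparison, 3 to 12 calls were false, and a list given a change of 0.5 was called in all 4 with no other list. In the real arrays genes of a list can correlate (estimated at 0.284 for the metallothioneins). The simulation therefore does not measure how often lists are falsely called there. Probe positions and sequences were not used here.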

Results

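Messenger RNA levels were measured on 32 one-colour expression bead arrays, in 8 groups of 4, from 2 human liver tumour cell lines. The labels describe Huh7 as a hepatocellular carcinoma line and HepG2 as a hepatoblastoma line. In 1 part of the series each line received SAHA (vorinostat, an inhibitor of histone deacetylases) or its solvent DMSO. In the other part each line received an siRNA against HDAC2, the gene of a class I histone deacetylase, or a scrambled siRNA. Between 48.3% and 54.9% of the probes of an array gave a signal above background, and 12973 genes were tested. The labels do not say whether the 4 arrays of a group came from separate cultures, so every p-value measures only the spread between arrays, and their number limits the precision of every value. All changes below are differences of mean log2 signal between 4 treated and 4 control arrays, with the standard error (SE) of the fitted model and a limma p adjusted by Benjamini-Hochberg over all genes tested.

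HDAC2 itself was read by 1 probe. With the siRNA its transcript fell by 3.34 on the log2 scale in Huh7, from 12.07 ± 0.04 to 8.73 ± 0.10 (SD, n = 4, limma adjusted p = 4.24e-21), which left 9.87% of the control level. In HepG2 the level fell by 3.05, from 10.97 ± 0.14 to 7.93 ± 0.23 (SD, n = 4, limma adjusted p = 2.45e-19), which left 12.1%. With SAHA, HDAC2 rose by 0.45 in Huh7 (11.95 ± 0.10 against 11.50 ± 0.13, SD, n = 4, limma adjusted p = 0.00035) and its change in HepG2 of -0.16 did not pass (limma adjusted p = 0.209). Both SAHA values depended on the scaling of the arrays: with each array scaled to one median they were 0.13 (adjusted p = 0.461) and -0.48 (adjusted p = 0.00387). In the siRNA comparisons, and with SAHA in Huh7, the 4 treated arrays did not overlap the 4 control arrays for HDAC2.

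**Figure D1:**
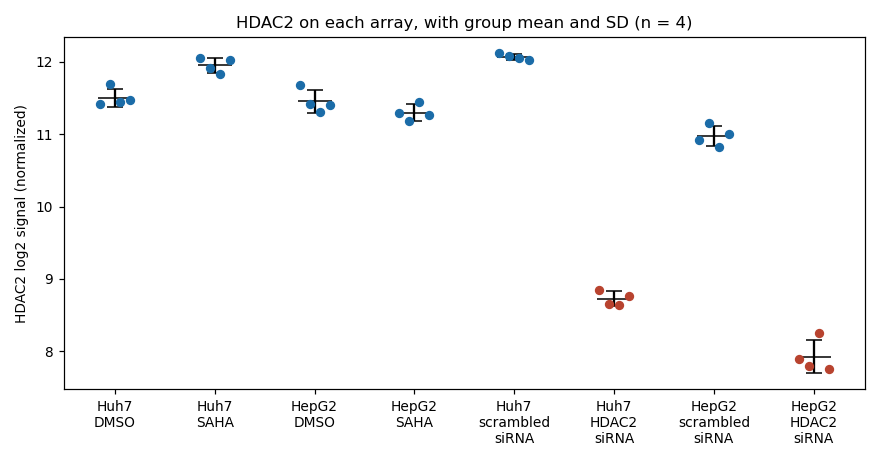
HDAC2 signal (log2) on each of the 32 arrays, by group; points are arrays and the bars give the mean ± SD of 4 arrays. The siRNA arrays lie near 8.73 in Huh7 and 7.93 in HepG2, below their scrambled controls at 12.07 and 10.97, while the means of the SAHA and DMSO groups lie between 11.30 and 11.95.

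The comparison of SAHA with DMSO in Huh7 asks which genes respond to broad inhibition of histone deacetylases. Among the largest rises, VGF, the gene of a neuropeptide precursor, rose by 5.99 (SE 0.17, adjusted p = 3.38e-23), and TMEM59L, TMEFF2 and ELOVL4 rose by 5.87, 5.82 and 5.24. DHRS2, a dehydrogenase gene, rose by a fitted 5.98 (SE 0.09, adjusted p = 2.41e-30); its control signal was not well above background on any array, so the rise was at least 40.04-fold. The largest falls were in NEU4, a sialidase gene (-4.97, SE 0.16, adjusted p = 1.16e-21), and in SCNN1A, a sodium channel subunit gene (-4.90, SE 0.14, adjusted p = 8.47e-23). The transporter gene SLCO2B1 fell at least 20.0-fold to a signal not well above background. Of 12973 genes, 4094 rose and 3774 fell (7868, or 60.6%), and 3129 of them changed at least 2-fold.

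The proliferation lists fell with SAHA in Huh7 and the histone list rose. Of 36 DNA replication genes tested, 31 fell and 1 rose (31 and 1 adjusted over the list alone), with TYMS at -3.53, MCM5 at -3.17 and CDT1 at -3.10. The median was -1.5, and limma camera gave adjusted p = 9.49e-12, or 0.00256 with an estimated correlation. Of 34 mitosis genes, 29 fell and 2 rose (30 and 2 adjusted over the list alone), with UBE2C at -2.66 and AURKA at -2.43 (median -1.09, adjusted p = 1.04e-09). Of 23 histone genes, 19 rose and 3 fell (the same counts adjusted over the list alone), with H1-2 at 3.81, H2AC18 at 4.03 and H2BC21 at 4.66 (median 2.34, adjusted p = 9.91e-09), although histone and metallothionein probes can bind transcripts of close relatives. Among 16 cell cycle inhibitors 11 rose and 3 fell, both counts also adjusted over the list alone, led by CDKN1A at 3.22 and GADD45A at 2.09 (median 0.73, adjusted p = 0.0272), a call lost with all detected probes tested singly (adjusted p = 0.134) and with the mean of a gene's probes (adjusted p = 0.055). Of 20 genes of the MYC and ribosome biogenesis list 17 fell and 2 rose, both counts also adjusted over the list alone, with NOP56 at -1.62 and MYCN at -3.63, while ODC1 rose by 1.57 (median -0.95, adjusted p = 0.000135).

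Liver genes fell with SAHA in Huh7. Of 36 hepatocyte genes, 30 fell and 2 rose (31 and 2 adjusted over the list alone). ASGR2, an asialoglycoprotein receptor gene, changed by -4.15 (adjusted p = 4.1e-25), the apolipoprotein gene APOB by -3.87 and ASGR1 by -2.89, and the list's median was -0.96 (adjusted p = 9.02e-10). Of 18 hepatocyte transcription factor genes 13 fell and none rose, also adjusted over the list alone, with NR0B2 at -3.31, CEBPA at -2.55 and FOXA1 at -2.21 (median -0.76, adjusted p = 0.000113). Of 17 oncofetal liver genes 10 fell and 4 rose (11 and 4 adjusted over the list alone), with IGF2BP3 at -1.85 and H19 at -1.84 (median -0.69, adjusted p = 0.0281); that call was lost with an estimated correlation between genes (adjusted p = 0.166 with an estimated correlation), with all detected probes tested singly (adjusted p = 0.0916) and among genes detected on all 32 arrays (adjusted p = 0.601). Of 9 metallothioneins, genes of metal-binding proteins, 7 rose, also adjusted over the list alone, led by MT2A at 2.96 and MT1G at 2.84 (median 1.87, adjusted p = 0.000145, adjusted p = 0.0867 with an estimated correlation). Of 21 neuronal genes 13 rose and 1 fell, both counts also adjusted over the list alone, with SYP at 3.59 and SYT11 at 2.82 (median 0.44, adjusted p = 0.000595), and that call was lost among genes detected on all 32 arrays (adjusted p = 0.233). Camera called 10 of 31 lists in this comparison, and 8 of them held with an estimated correlation.

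Among the other histone deacetylase genes, HDAC3 rose by 1.40 with SAHA in Huh7 (SE 0.10, adjusted p = 4.17e-13). HDAC1 rose by 0.39 (adjusted p = 0.000174), a call lost with each array scaled to one median (0.14, adjusted p = 0.284), and HDAC4 fell by 0.47 (adjusted p = 0.00389) with arrays that overlapped. Several scattered genes of stress and metabolism also moved far: NQO1, a quinone reductase gene and target of NRF2, fell by 3.34, and TRIB3, a stress-induced pseudokinase gene, fell by 2.90. With each array scaled to one median the median of all genes lay at -0.128, and 39.2% of the called genes were higher in place of 52%, so rises and falls in Huh7 with SAHA are relative to an equal distribution of signal on every array.

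With SAHA in HepG2, the question is the same in the second line, and genes of cell division were among those with the largest falls. KIF20A, a mitotic kinesin gene, changed by -4.88 (SE 0.09, adjusted p = 1.71e-27) and CCNA2, the cyclin A2 gene, by -4.83 (SE 0.15, adjusted p = 2.22e-22). CCNB2, RRM2 and CDC45 changed by -4.54, -4.39 and -4.38. All 34 mitosis genes fell, also adjusted over the list alone, with UBE2C at -4.24 and AURKA at -3.84 (median -3.30, adjusted p = 7.95e-30). Of 36 DNA replication genes 33 fell and none rose (34 and none adjusted over the list alone), with MCM4 at -3.54 and MCM7 at -3.05 (median -2.45, adjusted p = 3.91e-22, adjusted p = 0.000228 with an estimated correlation). S100A9, the gene of a calcium-binding protein of myeloid cells, rose by 8.31 (SE 0.18, adjusted p = 5.62e-26), from 5.31 to 13.63. The rise was 8.10 with the DMSO signals, detected on 2 of 4 arrays, raised to at least the lowest detected on each array. DEFB1, a defensin gene, rose at least 58.5-fold from a signal not well above background (6.47 fitted, adjusted p = 1.71e-27). ALPL rose by 5.21, and SMPDL3B rose at least 23.0-fold from such a signal. Of 12973 genes, 3497 rose and 3579 fell (7076, or 54.5%), and 2383 of them changed at least 2-fold. With each array scaled to one median the median of all genes lay at -0.171, and 32.3% of the called genes were higher in place of 49.4%.

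The neuronal genes and the leukocyte markers rose with SAHA in HepG2, and the cancer testis list and the fibroblast and endothelial list did not pass (adjusted p = 0.244 for each). Of 21 neuronal genes 13 rose and 1 fell, both counts also adjusted over the list alone, with SYT11, a synaptotagmin gene, at 4.42 and MAPT at 2.54, and SYN1 rose at least 5.83-fold from a signal not well above background (median 1.04, adjusted p = 6.66e-05). Of 9 leukocyte markers 5 rose, also adjusted over the list alone, among them CD3D by 4.82, CD14 by 3.19, CSF1R by at least 3.41-fold, and CD74, named after its values were seen, by 2.48 (median 2.48, or 1.77 with members not well above background at their bound, adjusted p = 0.000288). Of 17 WNT targets 12 rose and 1 fell, both counts also adjusted over the list alone, with NKD1 at 1.86 and NOTUM at 2.25 (median 0.62, adjusted p = 0.00429). Of 20 genes of the MYC and ribosome biogenesis list 13 fell and 2 rose, both counts also adjusted over the list alone, with NOP56 at -1.09 and ODC1 at -0.91 (median -0.56, adjusted p = 0.0115). Among genes detected on all 32 arrays these 4 calls were lost, with adjusted p = 0.894, 0.767, 0.278 and 0.0591 in that order, and the median of the neuronal genes was then -0.23.

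Further lists passed with SAHA in HepG2 at a preset correlation only. Of 16 NRF2 targets, genes of the oxidative stress response, 9 rose and none fell, also adjusted over the list alone, with SRXN1 at 2.95 and AKR1B10 at 1.92 (median 0.51, adjusted p = 0.00212, adjusted p = 0.0976 with an estimated correlation). Of 9 metallothioneins 6 rose, also adjusted over the list alone, led by MT1X at 1.39 (median 0.68, or 0.43 with dim members at their bound, adjusted p = 0.0231, adjusted p = 0.268 with an estimated correlation). Of 23 histone genes 11 rose and 4 fell (13 and 4 adjusted over the list alone), with H1-2 at 3.05 and H2BC12 at 3.12 and with H2AX at -2.96 (median 0.34, adjusted p = 0.0265, adjusted p = 0.134 with an estimated correlation and 0.278 among genes detected on all 32 arrays). Of 36 hepatocyte genes 16 fell and 4 rose, both counts also adjusted over the list alone, with ITIH2 at -2.05 and PROC at -1.76 (median -0.17, adjusted p = 0.0265, adjusted p = 0.221 with an estimated correlation). That call was also lost with all detected probes tested singly (adjusted p = 0.0607), with the mean of a gene's probes (adjusted p = 0.0618) and among genes detected on all 32 arrays (adjusted p = 0.34). CDKN1A rose by 1.67 (adjusted p = 5.9e-15), while the list of 16 cell cycle inhibitors, with 6 higher and 3 lower, did not pass (adjusted p = 0.325). HDAC11 rose by 1.08, and HDAC8 and HDAC1 changed by -0.93 and -0.31. HDAC3 rose by 0.62, a call lost with each array scaled to one median (0.25, adjusted p = 0.107). Camera called 10 of 31 lists, of which 6 held with an estimated correlation.

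**Figure D2:**
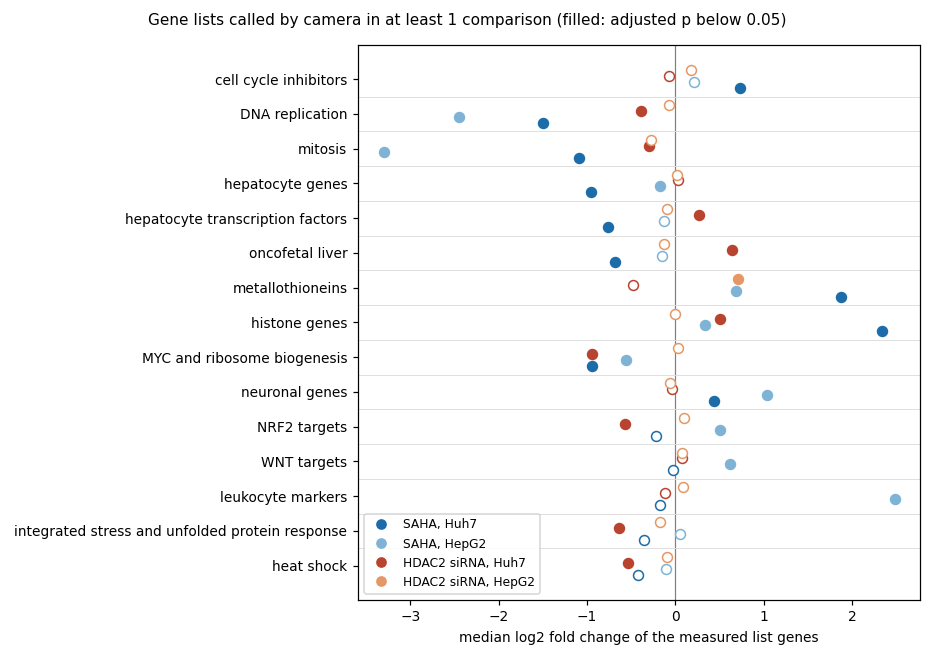
Median log2 fold change of each gene list called in at least 1 of the 4 treatment comparisons; each point is 1 list in 1 comparison (4 arrays against 4) and filled points passed limma camera at an adjusted p under 0.05. With SAHA the DNA replication medians lie at -1.5 (Huh7) and -2.45 (HepG2), and with HDAC2 siRNA in Huh7 the MYC and ribosome biogenesis median lies at -0.95.

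The SAHA effects of the lines were compared by an interaction contrast, the HepG2 effect minus the Huh7 effect, tested in the same limma model. S100A9 rose in HepG2 and fell in Huh7 to a signal not well above background, and DEFB1 rose at least 58.5-fold in HepG2 and fell by 2.03 in Huh7. Their fitted differences of 9.54 (adjusted p = 3.1e-23) and 8.503 (adjusted p = 1.48e-26) were 9.02 and 7.90 with each signal raised to at least the lowest detected on its array. SCNN1A fell by 4.90 in Huh7 and rose by 2.25 in HepG2 (difference 7.15). In the other direction DHRS2 rose at least 40.04-fold in Huh7 and fell by 0.91 in HepG2 (fitted difference -6.89, adjusted p = 1e-27, or -6.24 with signals raised in this way). TMEFF2 rose by 5.82 in Huh7 (5.57 with raised signals) and was detected on no DMSO or SAHA array of HepG2. Of 12973 genes, 6770 (52.2%) differed between the lines; 1048 of these were called in opposite directions, and 1877 were called in the same direction with unequal size. The mitosis genes fell further in HepG2, with 31 of 34 members lower and none higher by this test (median -1.97, adjusted p = 2.91e-16), and 20 of 23 histone genes rose less in HepG2 or fell (median -1.5, adjusted p = 5.71e-07). The hepatocyte genes were less lowered in HepG2, with 23 of 36 members higher and 4 lower by this test (median 0.69, adjusted p = 2.24e-06). The NRF2 targets were 10 higher and 1 lower of 16 (median 1.57, adjusted p = 3.89e-06). With an estimated correlation camera gave adjusted p = 2.41e-05 for the mitosis genes and 0.00159 for the histone genes. For the hepatocyte genes and for the NRF2 targets it gave 0.0111.

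Camera called 11 of 31 lists for this difference, and 8 held with an estimated correlation. The leukocyte markers had 6 of 9 members higher in HepG2 (median 2.30, adjusted p = 4.46e-05), a call that turned among genes detected on all 32 arrays (median -0.11, adjusted p = 0.955). The hepatocyte transcription factors had 11 of 18 higher and 2 lower (median 0.70, adjusted p = 0.00236), and the stress and unfolded protein response genes had 16 of 26 higher and 5 lower (median 0.58, adjusted p = 0.0288). The WNT targets had 11 of 17 higher and 2 lower (median 0.70, adjusted p = 0.00432), a call lost among genes detected on all 32 arrays (adjusted p = 0.0628). The DNA replication genes had 22 of 36 lower and 1 higher (median -0.69, adjusted p = 4.18e-05, adjusted p = 0.0765 with an estimated correlation). The metallothioneins had 6 of 9 lower and 1 higher (median -1.22, adjusted p = 0.0148, adjusted p = 0.221 with an estimated correlation). The p53 targets had 12 of 23 lower and 2 higher (median -0.56, adjusted p = 0.0398, adjusted p = 0.0942 with an estimated correlation). The call of the p53 targets was lost without Huh7 DMSO replicate 2 (adjusted p = 0.052), with all detected probes tested singly (0.125), with the mean of a gene's probes (0.11) and among genes detected on all 32 arrays (0.243). Adjusted over the list alone, the counts were 23 lower for DNA replication, 13 lower for the p53 targets, 24 higher for the hepatocyte genes and 17 higher for the stress and unfolded protein response genes, with the others equal to those over all genes. Across genes, the SAHA effects of the lines correlated at r = 0.426 (Spearman 0.427; jackknife SE over arrays 0.0117), where genes are not independent replicates, and at 0.42 to 0.456 under the alternatives that kept all arrays. SAHA raised 1932 genes in both lines (1104 for independent lists) and lowered 1937 in both (1041 for independent lists).

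**Figure D3:**
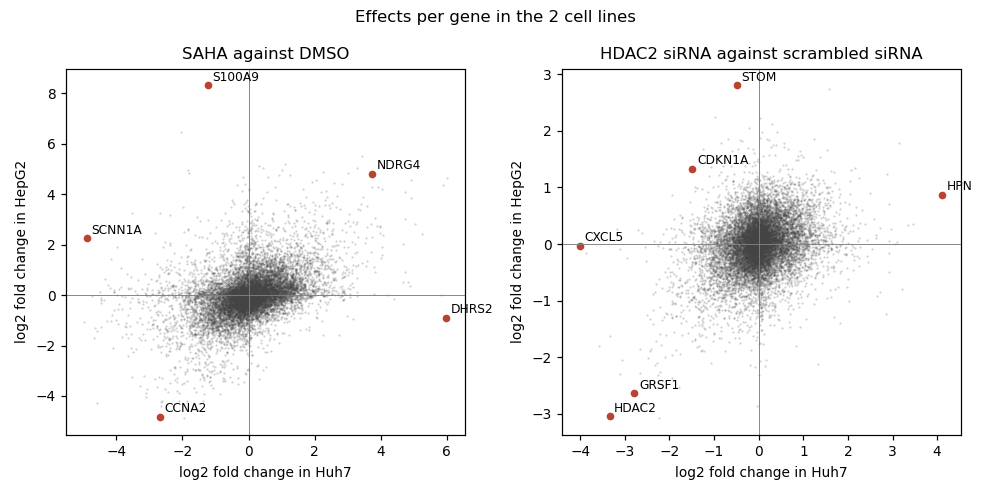
Effect in HepG2 (log2 fold change, vertical) against effect in Huh7 (log2 fold change, horizontal) for 12973 genes, SAHA on the left and HDAC2 siRNA on the right; each point is 1 gene from 4 arrays against 4 per line, and red points are named genes. The correlation across genes was 0.426 with SAHA and 0.284 with HDAC2 siRNA, and S100A9 (fitted values 8.31 in HepG2, -1.23 in Huh7) lies far from the diagonal.

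The comparison of HDAC2 siRNA with scrambled siRNA in Huh7 asks which genes respond to loss of this 1 deacetylase. Among the largest falls, CXCL5, a chemokine gene, changed by -4.00 (SE 0.11, adjusted p = 1.5e-22) and TMEM45A by -3.88 (SE 0.12, adjusted p = 2.23e-21). MTHFD2, a mitochondrial folate enzyme gene, changed by -3.57 (SE 0.14, adjusted p = 1.22e-18). HPN, the gene of the serine protease hepsin, rose by 4.12 (SE 0.16, adjusted p = 1.22e-18), and SPON2, DACT2 and PIK3IP1 rose by 3.46, 3.21 and 3.15. BMF, a pro-apoptotic gene, rose by 2.97 (SE 0.21, adjusted p = 4.26e-13). Of 12973 genes, 2975 rose and 2903 fell (5878, or 45.3%), and 1300 of them changed at least 2-fold (641 rose and 659 fell). With each array scaled to one median, 47.4% of the called genes were higher in place of 50.6%.

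Genes of ribosome biogenesis and of protein folding fell with HDAC2 siRNA in Huh7. Of 20 genes of the MYC and ribosome biogenesis list, 17 fell and 1 rose, both counts also adjusted over the list alone; DKC1, BOP1 and NOLC1 changed by -1.23, -1.37 and -1.16, MYC itself by -1.39, and the median was -0.95 (adjusted p = 6.81e-08). Of 26 stress and unfolded protein response genes 16 fell and 4 rose (17 and 4 adjusted over the list alone), with SDF2L1 at -1.57 and ASNS at -1.30 (median -0.63, adjusted p = 0.000348). Of 14 heat shock genes 11 fell and 1 rose (12 and 1 adjusted over the list alone), with HSPA1B at -1.08 and BAG3 at -1.31 (median -0.54, adjusted p = 0.00109). These 3 of the 9 lists called held with an estimated correlation. CCNG2 rose by 2.23 (adjusted p = 9.5e-15) while CDKN1A fell by 1.49 (adjusted p = 3.8e-13), and the cell cycle inhibitors as a list did not pass (5 of 16 higher, 4 lower, adjusted p = 0.711), with a median of -0.07 but a mean of 0.09 and a test pointing up.

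The other 6 lists called with HDAC2 siRNA in Huh7 were lost with an estimated correlation, and also among genes detected on all 32 arrays. Of 36 DNA replication genes 20 fell and 4 rose, both counts also adjusted over the list alone, with CDC45 at -1.05 (median -0.39, adjusted p = 0.00379, adjusted p = 0.236 with an estimated correlation and 0.0611 under the detection rule). Of 34 mitosis genes 15 fell and 3 rose (16 and 3 adjusted over the list alone), with CDC20 at -1.72 and PRC1 at 1.16 (median -0.30, adjusted p = 0.0261, adjusted p = 0.185 with an estimated correlation and 0.222 under that rule). Of 16 NRF2 targets 9 fell and 1 rose (9 and 2 adjusted over the list alone), with NQO1 at -1.95 (median -0.57, adjusted p = 0.00379, adjusted p = 0.132 with an estimated correlation and 0.133 under that rule). Of 23 histone genes 12 rose and 2 fell (13 and 2 adjusted over the list alone), with H2BC12 at 1.59 and H2BC21 at 2.24 (median 0.51, adjusted p = 0.00379, adjusted p = 0.0653 with an estimated correlation and 0.063 under that rule). Of 17 oncofetal liver genes 11 rose and 2 fell, both counts also adjusted over the list alone, with SOX9 at 1.39 and GPC3 at 1.06 and with LIN28B at -2.02 (median 0.64, adjusted p = 0.00838, adjusted p = 0.122 with an estimated correlation and 0.117 under that rule). Of 18 hepatocyte transcription factors 8 rose and 1 fell, both counts also adjusted over the list alone, with NR0B2 at 2.26 and RXRA at 1.36 (median 0.27, adjusted p = 0.0261, adjusted p = 0.111 with an estimated correlation and 0.0611 under that rule). Among the deacetylase genes, HDAC6 and HDAC3 rose by 0.69 and 0.58, and HDAC4 and HDAC1 changed by -0.72 and -0.39.

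With HDAC2 siRNA in HepG2, the same question in the second line, the effects were smaller. SPP1, the osteopontin gene, fell by 3.08 (SE 0.23, adjusted p = 6.89e-12), and MRAP, AGPAT9, GRSF1 and SAA4 changed by -2.87, -2.81, -2.64 and -2.53. STOM, a membrane scaffold gene, rose by 2.81 (SE 0.16, adjusted p = 4.66e-14), FILIP1L by 2.75 (SE 0.23, adjusted p = 5.4e-11), the cyclin gene CCND2 by 2.23 (SE 0.15, adjusted p = 1.04e-12) and the iron exporter gene SLC40A1 by 2.12. The fibrinogen genes FGA, FGG and FGB rose by 1.84, 1.58 and 2.06, whereas the hepatocyte gene list as a whole did not pass (8 of 36 higher, 9 lower, adjusted p = 0.963). CDKN1A and BTG2, both antiproliferative, rose by 1.33 and 1.86, and the cell cycle inhibitor list did not pass (6 of 16 higher, 2 lower, adjusted p = 0.298). Of 12973 genes, 2433 rose and 2315 fell (4748, or 36.6%), and 551 of them changed at least 2-fold (214 rose and 337 fell). With each array scaled to one median 57.6% of the called genes were higher in place of 51.2%. The 4 siRNA arrays of HepG2 varied more than any other group (median residual SD 0.239, against 0.131 to 0.187 in the others). The count of 4748 took 1 spread per gene over all 8 groups, so for this more variable group the adjusted p may be too small. The same spread served the contrasts that use this group. Array quality weights kept 3406 of these 4748 calls. With only the 8 arrays of this comparison in the model 2967 genes were called. Of the 31 lists camera called the metallothioneins alone, with 6 of 9 members higher, also adjusted over the list alone, led by MT1M at 1.51 and MT1E at 0.87 (median 0.71, adjusted p = 0.00584, adjusted p = 0.365 with an estimated correlation and 0.152 among genes detected on all 32 arrays). HDAC1, the closest relative of HDAC2, rose by 0.78 (adjusted p = 1.71e-08), and HDAC8 rose at least 1.43-fold from a signal not well above background (adjusted p = 0.000897), with arrays that overlapped. The HDAC8 call was lost with HepG2 HDAC2 siRNA arrays 1 and 2 only (fitted 0.52, adjusted p = 0.0865).

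The HDAC2 siRNA effects of the lines differed by the interaction contrast (HepG2 effect minus Huh7 effect) in 4825 genes (37.2%). CXCL5 fell by 4.00 in Huh7 and was detected on no siRNA or scrambled array of HepG2. CDKN1A, the gene of the cell cycle inhibitor p21, fell by 1.49 in Huh7 and rose by 1.33 in HepG2 (difference 2.82, adjusted p = 4.03e-15). PPARGC1A, a coactivator gene of mitochondrial and glucose metabolism, rose by 2.66 in Huh7 and fell by 0.93 in HepG2 (difference -3.58, adjusted p = 1.25e-13), and ADGRG1 rose by 2.86 and fell by 1.23 (difference -4.09, adjusted p = 4.03e-15). In all 735 of these genes were called in opposite directions, and 562 were called in the same direction with unequal size. The MYC and ribosome biogenesis genes fell less in HepG2 than in Huh7, or rose, with 17 of 20 members higher and none lower by this test (median 0.97, adjusted p = 1.18e-07), and the hepatocyte transcription factors had 11 of 18 members lower and 1 higher (median -0.90, adjusted p = 0.000526). These 2 of the 8 lists called held with an estimated correlation. Across genes the siRNA effects of the lines correlated at r = 0.284 (Spearman 0.245; jackknife SE over arrays 0.0199), and at 0.263 to 0.359 under the alternatives that kept all arrays. In both lines the siRNA raised 923 genes (558 for independent lists) and lowered 991 (518 for independent lists). At least 2-fold changes shared by the lines were 121 falls (17.1 for independent lists) and 34 rises (10.6 for independent lists), and the siRNA sequence is not given in the sources used here.

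The 6 other lists called for this siRNA difference were lost with an estimated correlation. The metallothioneins had 7 of 9 members higher in HepG2 than in Huh7 (median 1.22, adjusted p = 0.000232, adjusted p = 0.104 with an estimated correlation), and the NRF2 targets 9 of 16 (median 0.69, adjusted p = 0.00736, adjusted p = 0.134 with an estimated correlation). The stress and unfolded protein response genes had 13 of 26 higher and 3 lower (median 0.31, adjusted p = 0.0176, adjusted p = 0.0517 with an estimated correlation), and the histone genes 9 of 23 lower and 2 higher (median -0.45, adjusted p = 0.0176, adjusted p = 0.104 with an estimated correlation). The heat shock genes had 6 of 14 higher (median 0.34, adjusted p = 0.0327, adjusted p = 0.0689 with an estimated correlation), a call lost without Huh7 scrambled siRNA replicate 1 (adjusted p = 0.0506). The oncofetal liver genes had 7 of 17 lower and 3 higher (median -0.52, adjusted p = 0.0384, adjusted p = 0.193 with an estimated correlation). That call was lost without HepG2 HDAC2 siRNA replicate 2 (adjusted p = 0.0737), with each array scaled to one median (0.129) and with the authors' normalized values (0.0714). Adjusted over the list alone, 10 NRF2 targets and 14 stress genes were higher, 12 histone genes, 10 oncofetal liver genes, 1 NRF2 target and 1 gene of the MYC and ribosome biogenesis list were lower, and the other counts were equal to those over all genes. Among genes detected on all 32 arrays the NRF2, stress, histone, heat shock and oncofetal calls were lost too, with adjusted p = 0.115, 0.0942, 0.0942, 0.166 and 0.235.

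The SAHA and HDAC2 siRNA effects of each line were compared to ask how far loss of 1 deacetylase resembles inhibition of many; the comparisons share no control array. The thioredoxin inhibitor gene TXNIP rose in all 4 comparisons, by 4.07 and 2.38 with SAHA in Huh7 and HepG2 and by 1.38 and 1.54 with HDAC2 siRNA in the same order. ZSWIM4 rose by 1.26, 2.05 and 1.63 and at least 2.03-fold, the phosphatase gene DUSP5 by 1.10, 2.86, 1.15 and 1.13, and the tubulin gene TUBB2B by 1.23, 2.85, 2.04 and 0.89. The acute phase gene SAA4, whose probe can bind transcripts of close relatives, changed by -4.29 with SAHA and -2.53 with the siRNA in HepG2. In Huh7 SAA4 fell at least 17.8-fold and 2.76-fold to signals not well above background. ICAM3 changed by -1.49, -1.54, -1.85 and -1.28, and FAM136A by -2.41, -2.20, -2.51 and -1.26. PPARG, a nuclear receptor gene of lipid storage, changed by -1.17, -1.30, -2.42 and -1.85, the ribosomal RNA methyltransferase gene DIMT1 by -1.39, -1.54, -2.37 and -1.16, and the replication gene MCM10 by -1.87, -3.40, -1.14 and -1.25. ATAD3B ranked among these genes too, but its siRNA call in HepG2 was lost with HepG2 HDAC2 siRNA arrays 1 and 2 only (-0.67, adjusted p = 0.0523). All told, 241 genes rose in all 4 comparisons (47.5 for 4 independent lists) and 281 fell in all 4 (41.6 for 4 independent lists). These expected counts also take the lines as independent under the same treatment, which they were not. They therefore overstate the excess that SAHA and the siRNA share. CDKN1A rose in 3 comparisons and fell with HDAC2 siRNA in Huh7.

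Most effects of SAHA were not shared with the siRNA. Across genes r was 0.115 in Huh7 (Spearman 0.131; jackknife SE over arrays 0.0113) and 0.118 in HepG2 (Spearman 0.12; jackknife SE over arrays 0.0165). Under the alternatives that kept all arrays they ran from 0.11 to 0.122 and from 0.102 to 0.145. In Huh7 both treatments raised 1214 genes (939 for independent lists) and lowered 1285 (845 for independent lists), and 1740 were called in opposite directions (1782 for independent lists). In HepG2 both raised 886 genes (656 for independent lists) and lowered 913 (639 for independent lists), and 1215 were called in opposite directions (1295 for independent lists). The contrast of SAHA effect minus siRNA effect called 7105 genes in Huh7 (3767 higher, 3338 lower) and 6321 in HepG2 (3138 higher, 3183 lower). With each array scaled to one median, 41.6% of these calls in Huh7 were higher in place of 53%, and 31.6% in HepG2 in place of 49.6%, where the median of all genes lay at -0.213.

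**Figure D4:**
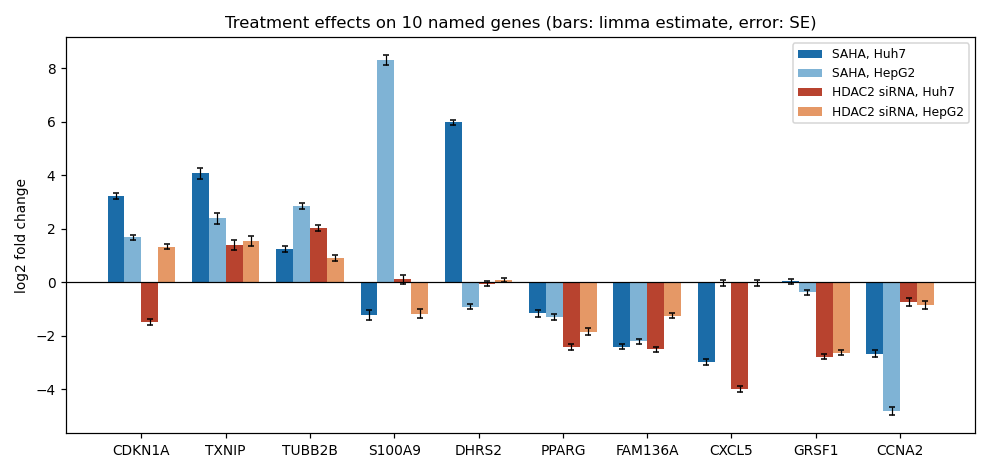
Log2 fold change of 10 named genes in the 4 treatment comparisons; bars are differences of means of 4 treated and 4 control arrays and error bars are standard errors of the limma model. TXNIP and TUBB2B rose and PPARG and FAM136A fell in all 4 comparisons, CDKN1A fell by 1.49 with HDAC2 siRNA in Huh7 alone, and S100A9 rose by a fitted 8.31 with SAHA in HepG2.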

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

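The tests on the excess of shared falls with HDAC2 siRNA, on abundant leukocyte genes, on a knockdown of unequal strength, on the difference of 2 pairs of arrays and on other splits of the arrays were chosen only after the results they concern were seen. Each difference between the lines given here was tested as the HepG2 effect minus the Huh7 effect in the limma model.

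Effects that differed between the cell lines stood out for a closer look. With SAHA 6770 genes differed between the lines, and no relabelling of treated and control arrays among the other 99 of 100 drawn gave as many (the highest gave 5010). Such relabelling removes the treatment effect of each line as well as the difference between them. It therefore cannot decide whether the lines differed by chance. With HDAC2 siRNA 4825 genes differed (the highest other relabelling gave 3680), with the same limit. The largest positive fitted SAHA differences were 9.54 for S100A9, 8.503 for DEFB1, 7.15 for SCNN1A, 6.80 for CLRN3 (which fell in Huh7 and rose by 3.27 in HepG2), 6.78 for SLC7A7, 6.63 for CD3D, 5.94 for MLLT11 and 5.90 for AKR1B10. In the other direction DHRS2 gave -6.89, TMEFF2 -5.81, MIR7-3HG -4.55, DNER -4.52, FTCD -4.34, HIST1H2BG -4.32, KCNAB1 -4.18 and TJP3 -4.14. These sizes are uncertain where signals lay near background: with each signal raised to at least the lowest detected on its array they were 9.02 for S100A9, 7.90 for DEFB1, 6.40 for SLC7A7, 5.42 for AKR1B10 and -6.24 for DHRS2. Of the 8 DMSO and SAHA arrays of HepG2, TMEFF2 was detected on none, MIR7-3HG on 1, and DNER and KCNAB1 on 2 each, so no effect was measured there. FTCD and TJP3 are liver and epithelial genes that rose with SAHA in Huh7 and changed by -1.60 and -0.97 in HepG2.

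With HDAC2 siRNA the largest positive fitted differences between the lines were 3.97 for CXCL5, 3.72 for TMEM45A, 3.45 for CIDEC, 3.30 for STOM, 3.03 for OLR1, 2.95 for CXCL10, 2.82 for NPPB and 2.82 for CDKN1A. CXCL5, OLR1 and CXCL10 were detected on no siRNA or scrambled array of HepG2 and TMEM45A on 1 of 8, so these 4 differences rest on falls in Huh7 beside no measured effect in HepG2. CIDEC, a lipid droplet gene, fell in Huh7, and its change of 0.27 in HepG2 did not pass (limma adjusted p = 0.297). The largest negative differences were -4.09 for ADGRG1, -4.00 for DACT2, -3.58 for PPARGC1A, -3.58 for TRIM50 (-3.04 with signals raised as above), -3.45 for TJP3, -3.41 for MMP11, -3.25 for HPN (which rose in both lines) and -3.23 for GDPD5.

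For the comparisons within a line, the 8 arrays were split into 4 and 4 in 35 ways. In each comparison only the real grouping called as many genes, which is the smallest share that 35 splits can give. This argues against a chance division of the arrays. It cannot exclude a chance difference between cultures, as the labels do not say whether the arrays of a group came from separate cultures. SAHA in Huh7 called 7868 genes against 2355 in the highest other split, and SAHA in HepG2 called 7076 against 7. The siRNA in Huh7 called 5878 against 1256, and in HepG2 4748 against 1496. For the SAHA effect minus the siRNA effect the real labels called 7105 genes in Huh7 and 6321 in HepG2. The highest other of 100 relabellings gave 5482 and 5766. These relabellings also remove the effect of each treatment, so they cannot decide whether the treatments differed by chance.

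Single arrays lay far from the other 3 of their group in 13 of 224 groups of values tested, where chance flags about 1 in 20, or 11.2 groups. Of these, 2 were shares of probes detected, 52.9% on Huh7 DMSO replicate 4 (51.7% to 51.9% on the others) and 48.3% on HepG2 HDAC2 siRNA replicate 4 (50.01% to 50.18%). The lowest correlation with another array of the group was 0.990 for HepG2 scrambled siRNA replicate 2 (0.989 for the others) and 0.982 for HepG2 HDAC2 siRNA replicate 3 (0.979 for the others). Both flagged values are higher than those of the other arrays. Arrays of a group share their pairwise correlations, so the rate of 1 in 20 does not hold for this measure. Low signals near background made up 4 cases: TMEFF2 at 5.50 (others 4.99 to 5.04) and DNER at 5.47 (4.94 to 4.96) on Huh7 DMSO replicate 4, HSD17B2 at 4.60 (4.88 to 4.92) on Huh7 SAHA replicate 4, and DEFB1 at 5.08 (4.68 to 4.74) on HepG2 DMSO replicate 3. With the siRNA, MTHFD2 lay at 6.44 on Huh7 HDAC2 siRNA replicate 3 (6.19 to 6.21), and RAI14 at 8.31 on Huh7 HDAC2 siRNA replicate 1 (8.40 to 8.41). RAI14 also lay at 10.95 on Huh7 scrambled siRNA replicate 1 (11.55 to 11.65), ACOX2 at 9.51 on Huh7 scrambled siRNA replicate 2 (9.20 to 9.22), and HSPB8 at 6.33 on HepG2 HDAC2 siRNA replicate 1 (7.19 to 7.24).

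The HDAC2 siRNA lowered 121 genes at least 2-fold in both lines, where independent lists would share 17.1, and raised 34 at least 2-fold in both, where they would share 10.6. The excess was 7.07-fold for falls and 3.22-fold for rises, a ratio of 2.20. Unintended targets of the siRNA that both lines share stayed open, as this ratio restates the excess of falls that drew attention to these genes and decides nothing. Shared falls that follow from loss of HDAC2 activity stayed open too: the median SAHA change of these genes was -0.196 in Huh7 (bootstrap SE 0.129) and -0.159 in HepG2 (bootstrap SE 0.0858), neither a clear fall nor clearly none. With SAHA 55 of them also fell and 43 rose in Huh7, and 51 fell and 38 rose in HepG2. Over all 12973 genes 3774 fell and 4094 rose in Huh7, and 3579 fell and 3497 rose in HepG2. Falls thus made up a larger share of the 121 genes than of all genes, and rises a slightly larger share. The 121 genes include HDAC2 itself. The sequence of the siRNA, and whether 1 or several were used, is not given in the sources used here.

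Of the 9 leukocyte markers tested (of 16 listed, none in another list, and all 9 detected in these lines on at least 4 arrays) 5 rose with SAHA in HepG2. Leukocytes or their RNA are argued against by abundant leukocyte genes: 1 of 6 rose by at least 1 on the log2 scale, CD74 by 2.48, while PTPRC (0.14), HLA-DRA (-0.01), CD3E (0.07) and CD2 (-0.26) stayed near background beside a rise of 4.82 in CD3D, and LYZ, high in the DMSO arrays, changed by 0.52 (adjusted p = 0.0719). A lift of dim probes by background is argued against for the 5 markers, which were picked because they rose. Their median change was 3.19 with the main settings and 2.23 without background correction. Their median signal with SAHA lay 5.18 above the lowest detected on the log2 scale. Under median scaling the change was 2.88, which decides little about scaling. That setting moved the median of all genes only from -0.0121 to -0.171, so it could hardly have come out otherwise. Transcription of these genes in HepG2 under SAHA is a hypothesis that remains, found on these data and not itself tested.

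The 4 HepG2 HDAC2 siRNA arrays were seen in the data to lie apart as 2 pairs: residuals correlated at 0.0745 between arrays 1 and 2 and at 0.0327 between 3 and 4, and at -0.485 to -0.558 across the pairs. Residuals about the mean of 4 arrays are negatively correlated by construction. The highest value in any other group was -0.0991, in Huh7 SAHA, where the lowest was -0.529. They were compared as individual samples. RNA of the other line is argued against as the main cause. The deviation of an array from the group mean correlated across genes with the difference of the lines at no more than 0.082 in size (jackknife SE 0.0256). That correlation was negative for arrays 1 and 2 and positive for 3 and 4, and the difference of the 2 pairs gave -0.096. A small share of such RNA was not excluded, as no mixture was simulated to show what correlation it would give. A knockdown of unequal strength may contribute and stayed open. The largest correlation of an array's deviation with the siRNA effect in HepG2 was 0.278 in size (jackknife SE over arrays 0.0988). The difference of the 2 pairs correlated with that effect at -0.217. HDAC2 lay at 7.90, 7.80, 8.25 and 7.75. A first version against the Huh7 effect gave at most 0.0426. It could not have reached its threshold, as the effects of the lines correlate at 0.284. Array-wide signal gave at most 0.0117, under the bound set beforehand to exclude it, but that bound was wrong because quantile normalization fixes this outcome. Before normalization the median signals of arrays 1 and 2 (172.5 and 169.4) lay between those of 3 and 4 (180.7 and 167.4), while their shares of probes detected (50.016% and 50.179%) lay above the others (50.012% and 48.28%), by a narrow margin over array 3, so it stayed open too. No biological explanation was tested, as the labels give these arrays nothing that sets them apart.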

How the results depend on the processing

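The alternatives were set before the data were examined, except the pair that kept only arrays 1 and 2, or only 3 and 4, of HepG2 HDAC2 siRNA, and the use of the main probe of each gene under the other normalizations, both chosen after seeing the data. Leaving out each array in turn gave 7565 to 7657 genes for SAHA in Huh7 and 6701 to 6796 in HepG2, 5453 to 5692 for HDAC2 siRNA in Huh7 and 4271 to 4863 in HepG2. It gave 6482 to 6648 for the SAHA line difference, 4470 to 4930 for the siRNA line difference, and 6828 to 7106 and 6091 to 6411 for SAHA against siRNA in Huh7 and HepG2. HDAC2 ran from 0.42 to 0.51 and from -0.21 to -0.08 with SAHA in Huh7 and HepG2, and from -3.38 to -3.31 and from -3.16 to -2.99 with the siRNA. Lists called numbered 10, 10, 9 and 1 in the 4 comparisons each time, 10 to 13 for the SAHA line difference and 7 to 9 for the siRNA one. No background correction, normalization within one line, the authors' normalized values, no detection filter, all probes singly, the mean of probes, array weights, an intensity trend and the replicate block kept the counts of genes and lists within 1.5 times and HDAC2 on its side of the threshold. The replicate block gave 7812, 7036, 5764 and 4595 genes in the 4 comparisons, and array numbers did not pair arrays: residuals of like numbers correlated at -0.14 to 0.261. A change of at least 2-fold left 3129 and 2383 genes with SAHA in Huh7 and HepG2, 1300 and 551 with the siRNA, 3098 and 1517 for the line differences, and 3655 and 2825 for SAHA against siRNA, and HDAC2 with SAHA in Huh7 (0.45) no longer passed, as the rule's construction requires. Fry, which asks whether a list's genes move on balance one way and compares them with no other genes, called 24, 25, 27 and 17 lists in the 4 comparisons and 25 and 23 for the line differences, and turned the direction of the glycolysis list with SAHA in Huh7 (median -0.0153, mean 0.351, adjusted p = 1.18e-05). An estimated correlation left 6 lists with SAHA in HepG2, 3 and 0 with the siRNA in Huh7 and HepG2, and 2 for the siRNA line difference; an adjusted p under 0.01 left 6 with SAHA in HepG2 and 4 for that difference. With each array scaled to one median, HDAC2 with SAHA was 0.13 in Huh7 and -0.48 in HepG2, BAG3 with SAHA in HepG2 turned to -0.0161 (adjusted p = 0.937), and the siRNA in HepG2 had 2 lists, in each case with a cause that was not tested. Detection on all 32 arrays, which leaves out dim genes, left 7255 genes tested, 4390 of them in the SAHA line difference. Camera then called 4 lists with SAHA in HepG2, 4 and 0 with the siRNA in Huh7 and HepG2 and 3 for the siRNA line difference. Of the 4 with the siRNA in Huh7, 1 was not called with the main settings. The leukocyte markers turned to -0.107 (adjusted p = 0.955) in the SAHA line difference, and the cancer testis list and the fibroblast and endothelial list had no genes left. With only the 8 arrays of the comparison, the siRNA in HepG2 called 2967 genes, with a cause that was not tested; arrays 1 and 2 alone called 3927, of which 3258 were shared with all 4, and arrays 3 and 4 alone called 4893 (3886 shared) and 2 lists. Among called changes of at least 2-fold, 1 group was not detected on any array for 251 rises and 125 falls with SAHA in Huh7. In HepG2 this held for 328 rises and 81 falls with SAHA. With the siRNA it held for 35 rises and 23 falls in Huh7 and for 7 and 11 in HepG2. Signal over background limits the sizes of these changes.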

Other observations

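Genes of lipid and sugar metabolism moved in both directions in most comparisons, and none of these lists passed limma camera. Of 21 genes of PPAR and fatty acid oxidation 10 rose and 7 fell with SAHA in Huh7 (adjusted p = 0.876), with PLIN2 at -2.91, and 9 rose and 8 fell in HepG2 (0.974), with ACAA1 at -1.95 and CPT1A at 1.55. With HDAC2 siRNA 6 rose and 9 fell in Huh7 (0.662), with PPARG at -2.42 and PPARGC1A at 2.66, and 3 rose and 8 fell in HepG2 (0.347), with PPARG at -1.85. Of 21 fatty acid synthesis genes 8 rose and 6 fell with SAHA in Huh7 (0.995), led by the lipid regulator SREBF1 at 2.15 and GPAM at -2.72, and 10 rose and 2 fell in HepG2 (0.0925), with LPIN1 at 1.45. With the siRNA the counts were 8 and 5 in Huh7 (0.546), with FADS1 at 1.56, and 3 and 7 in HepG2 (0.432), with GPAM at -1.75. Of 24 cholesterol synthesis genes 10 rose and 9 fell with SAHA in Huh7 (0.68), with INSIG1 at 2.66, and 6 rose and 7 fell in HepG2 (0.723), with EBP at -1.28. With the siRNA 7 rose and 4 fell in Huh7 (0.711), with TM7SF2 at 1.86 and a median of -0.04 beside a mean of 0.09, and 8 rose and 4 fell in HepG2 (0.963), with SQLE and IDI1 at -1.14 and -1.24 and a median of 0.03 beside a mean of -0.04.

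The hexokinase gene HK1 rose with SAHA in both lines, by 4.90 in Huh7 and 4.57 in HepG2, and the glucose transporter gene SLC2A3 by 4.66 in Huh7. The glycolysis and glucose transport list of 24 genes did not pass, with 7 higher and 9 lower in Huh7 (adjusted p = 0.969) and 10 higher and 11 lower in HepG2 (0.755). With the siRNA it had 3 higher and 7 lower in Huh7 (0.625), led by SLC2A1 at -1.27, and 4 higher and 8 lower in HepG2 (0.579), led by SLC2A2 at -1.30. The gluconeogenesis list of 9 genes gave 2 higher and 4 lower with SAHA in Huh7 (0.875), 5 higher in HepG2 (0.341), 5 higher and 2 lower with the siRNA in Huh7 (0.219) and 3 higher and 2 lower in HepG2 (0.886). Of 26 insulin and mTOR signalling genes 8 rose and 9 fell with SAHA in Huh7 (0.957), with PDPK1 at 1.10, and 6 rose and 8 fell in HepG2 (0.583), led by TSC2 at -1.10. With the siRNA 6 rose and 3 fell in Huh7 (0.288), led by PIK3CB at -1.47, and 4 rose and 5 fell in HepG2 (0.886).

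Apoptosis genes changed singly. The pro-apoptotic gene BID fell with SAHA by 3.57 in Huh7 and by 2.09 in HepG2, TNFRSF10B rose by 1.10 in Huh7, and BIK rose at least 2.79-fold in Huh7 and at least 16.3-fold in HepG2 from signals not well above background. The 21 pro-apoptotic genes were 8 higher and 7 lower with SAHA in Huh7 (adjusted p = 0.914, median -0.03 and mean -0.02 beside a test pointing up) and 5 higher and 6 lower in HepG2 (0.83, median -0.16 beside a mean of 0.07), and 1 higher and 7 lower with the siRNA in Huh7 (0.546) and 6 higher and 1 lower in HepG2 (0.807). The 11 anti-apoptotic genes were 3 higher and 6 lower with SAHA in Huh7 (0.333), with CFLAR at -2.19, 2 higher and 3 lower in HepG2 (0.496, median 0.06 beside a mean of -0.42), with BIRC5 at -3.29, and 2 higher and 2 lower with the siRNA in Huh7 (0.743) and 4 higher in HepG2 (0.347). The 23 p53 targets were 12 higher and 3 lower with SAHA in Huh7 (0.12), 4 higher and 6 lower in HepG2 (0.723), 5 higher and 4 lower with the siRNA in Huh7 (0.844) and 9 higher and 2 lower in HepG2 (0.144).

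Of 24 interferon response genes 8 rose and 6 fell with SAHA in Huh7 (adjusted p = 0.859) and 11 rose and 3 fell in HepG2 (0.23), with IFI6 at 3.47 and 3.89. With the siRNA 6 rose and 5 fell in Huh7 (0.83, median 0.03 beside a mean of -0.11), led by CXCL10 at -2.71, and 4 rose and 3 fell in HepG2 (0.963), led by MX2 at -1.30. Of 20 epithelial and mesenchymal genes 7 rose and 8 fell with SAHA in Huh7 (0.876), with CLDN1 at -1.78, and 10 rose and 3 fell in HepG2 (0.128), with CDH1, the E-cadherin gene, at 3.48 and FN1 at 2.84. With the siRNA 5 rose and 3 fell in Huh7 (0.711) and 5 rose and 2 fell in HepG2 (0.807). Of 22 corepressor genes 7 rose and 8 fell with SAHA in Huh7 (0.845), with GPS2 at 1.20 and KDM1A at -0.79, and 3 rose and 12 fell in HepG2 (0.119), with KDM1A at -0.93. With the siRNA 7 rose and 4 fell in Huh7 (0.616), with KDM1A at 0.76, and 5 rose and 4 fell in HepG2 (0.963), with MBD2 at 1.48. The 11 genes of the HDAC family as a list did not pass, with adjusted p = 0.847 and 0.83 with SAHA in Huh7 and HepG2 and 0.662 and 0.963 with the siRNA.

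Lists called in some comparisons did not pass in others. With SAHA in Huh7 the NRF2 targets were 3 higher and 6 lower (adjusted p = 0.135), the stress and unfolded protein response genes 7 higher and 14 lower (0.161), the heat shock genes 4 higher and 9 lower (0.225), the WNT targets 4 higher and 6 lower (0.845), and the leukocyte markers 3 higher and 3 lower (0.574). With SAHA in HepG2 the hepatocyte transcription factors were 2 higher and 8 lower (0.288), the oncofetal liver genes 4 higher and 8 lower (0.724), the stress genes 9 higher and 6 lower (0.625) and the heat shock genes 5 higher and 7 lower (0.552). With the siRNA in Huh7 the hepatocyte genes were 17 higher and 6 lower (0.219), the metallothioneins 1 higher and 5 lower (0.0954), the WNT targets 7 higher and 1 lower (0.168), the neuronal genes 4 higher and 1 lower (0.743, median -0.04 beside a mean of 0.01) and the leukocyte markers 2 lower (0.287). With the siRNA in HepG2 the mitosis genes were 13 lower and 2 higher (0.144), the DNA replication genes 9 lower and 4 higher (0.347), the stress genes 13 lower and 4 higher (0.159), the hepatocyte transcription factors 6 lower (0.28), the heat shock genes 6 lower and 2 higher (0.347), the histone genes 7 lower and 4 higher (0.963), and the genes of MYC and ribosome biogenesis 3 lower and 2 higher (0.963).

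The last 3 lists served as a check on cell identity and scaling. Of 6 cancer testis genes tested 1 rose with SAHA in Huh7, PAGE1 at least 1.86-fold, and 3 in HepG2, led by PRAME at 2.07 (adjusted p = 0.847 and 0.244). For MAGEA1 and MAGEB2 among these 3 the treated and control arrays overlapped. In the siRNA comparisons 2 were higher in Huh7 and 1 was lower in HepG2 (0.667 and 0.941). Adjusted over the list alone 1 was higher in Huh7, where the PRAME call was also lost without any 1 of the 4 HDAC2 siRNA arrays or of scrambled siRNA replicates 2, 3 and 4 (adjusted p = 0.0527 to 0.105), and in HepG2 the MAGEB2 call was lost without scrambled siRNA replicate 2 or 3 (0.0729 and 0.0552). Of 10 fibroblast and endothelial markers 5 rose and 1 fell with SAHA in Huh7 (0.26), led by COL1A2 at 2.60, and 3 rose in HepG2 (0.244), led by CDH5 at least 2.23-fold, while none changed with the siRNA in Huh7 (0.906) and 1 rose in HepG2 (0.807). Of 15 reference genes 4 rose and 5 fell with SAHA in Huh7 (0.876), led by HPRT1 at 1.32 and ACTB at -0.91, and 3 rose and 7 fell in HepG2 (0.496), led by B2M at 1.05; with the siRNA 3 rose and 4 fell in Huh7 (0.537) and 5 rose and 2 fell in HepG2 (0.347). For ACTB with the siRNA in HepG2 (0.31) another probe of the gene was called in the opposite direction. No hypothesis beyond those weighed above was tested.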
